A study of Oryzias latipes with 50 samples.

How the data were processed

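The series holds 50 RNA-seq libraries from a medaka brain block of ventral telencephalon, hypothalamus and pituitary, 2 from each of 25 sampling dates. Per the labels' protocols, the fish were kept outdoors, RNA was treated with DNase, mRNA was selected with poly-T beads, and strand-specific paired-end libraries with reads of 100 bases were made. The submitters' processing notes name Bowtie2 2.2.5 and RSEM 1.2.12 with no role for either. The genome build and annotation are not given in the sources used here, so no coordinates are printed. The authors deposited FPKM values, fragment abundance scaled by transcript length and library size, for 23455 genes with 1 column per library. No scaling between libraries beyond the FPKM itself is stated in the labels. The table pairs gene identifiers with symbols for all but 1547 genes, and 11586 of these symbols are LOC numbers. Of the identifiers, 21908 were found in the RefSeq gene table of assembly ASM223467v1, which was used for names only. A further 99 genes were matched by hand to list entries from their descriptions before any test.

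From these values, log2(FPKM + 1) was computed per library, and the 2 libraries of a date were averaged, since they may share that date's conditions. Genes with a mean of at least 1 FPKM over all libraries were tested, 16493 in all. Models were fitted with limma 3.58.1 in R 4.3.3, with a variance trend, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, and tables prepared with pandas 2.3.3.

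Of the comparisons, 6 were fitted across all genes. They were an annual cosine and sine over 25 dates; June to August against December to February; August to October against February to April; the second year against the first with the calendar month as a block (12 dates each, September 2015 left out); a 6-month wave added to the annual one; and a difference of the annual curve between years over 24 dates. The seasonal contrasts were fitted with the means of 4 blocks of 3 months over all 25 dates. The repeat of the peak date was counted from fits of each year alone. Day length was computed from the date and the latitude.

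Gene lists were fixed before the data were examined, as were the comparisons, the naming rule and the alternatives except those named last. They cover pituitary hormones and identity, photoperiod and thyroid hormone, hypothalamic neuropeptides, the clock, sex steroids, cold-inducible and chaperone genes, fatty acid and cholesterol synthesis, proliferation, NRF2, interferon, immediate early genes, opsins, retina and pineal, 8 further sets of cell type markers, ribosomal proteins, oxidative phosphorylation, and insulin and growth. The lists of at least 5 tested genes went through camera of limma, with a correlation of 0.01 and again with an estimated one. Lists of midbrain and hindbrain and of telencephalon markers were written later, after the fall of gnrh2 was seen and before their own test at the July 2016 step.

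The naming rule took the pituitary hormones and a fixed set of photoperiod, reproductive and clock genes whatever their result. For both seasonal contrasts it added the 10 largest changes in each direction among genes with a symbol, an adjusted p under 0.05, the same sign in both years and at least 5 FPKM in the higher group. For the other comparisons it took the 5 with the smallest adjusted p, in each direction where there is one, and for each list up to 4 members with the smallest adjusted p. Exceptions are the 3 genes without a symbol in the comparison of annual curves, arntl2 in summer against winter, and gnrh2, rln3a, zic1, dlx5 and dlx2 from the later lists, all chosen after their values were seen.

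The read counts behind the values were not used here. Relative depth was inferred from 105 genes whose smallest values are multiples of a common step, over 902 values, of which 84.9% lay within 10% of a whole multiple. It gives relative depth only, so no counting interval or detection limit is given, and a value of 0 is reported as listed. Some zeros may be failed estimates, since some abundant genes are at 0 in part of the libraries. Reads shared between copies of a gene, such as the cry1, tshb and globin genes, were not separated beyond the deposited values. The replicate numbers 1 and 2 carry no stated pairing. Both September 2015 titles carry the number 1, and these libraries were numbered in their listed order and left out of the replicate block.

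The models were tested on simulated data with the real genes' means and spread and 200 changed genes among 16493. At a 2-fold change they recovered 94.5% of seasonal genes, 93.5% for summer against winter, 96% for falling against rising days, 99.5% between years, 94% for the 6-month wave and 50% for the difference of annual curves. At a 1.5-fold change the last recovered 5%. In the simulated data, wrong calls made up at most 8.3% of calls in any of these settings or at 4-fold. In the real data libraries of neighbouring dates were more alike, with a median correlation of 0.9711 against 0.9499 for all different dates. Means and spread alone do not carry this likeness, so the rates of recovery and of wrong calls need not hold for the real data.

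Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, quantile normalization, scaling of each library to the same median log2 ratio, libraries as separate samples, the date as a random effect, the replicate number as a block, other months, a 2-fold threshold, and each library left out in turn. Added after seeing the data were a term for dates from July 2016, the dates before or after that step alone, and the July to September pairs for the year comparison.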

Results

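The data describe gene expression in a block of medaka brain (Oryzias latipes) that holds the ventral telencephalon, the hypothalamus and the pituitary. The fish lived outdoors under natural light and temperature in Okazaki, Japan, at 35.0 degrees north. The block was sampled about once a month at around 8 pm, on 25 dates from September 2015 to September 2017, with 2 libraries per date and 50 libraries in all. The design text asks how each gene is expressed over the year. Values are the deposited FPKM, which is read abundance scaled by transcript length and library size. Their sum ran from 278558 to 341666 per library over 23455 genes. No read totals were used here. A relative depth inferred from the smallest steps in the values of 105 genes ran from 0.849 to 1.087, so libraries differed little in depth. The labels do not say whether a library is 1 fish or a pool, nor its sex, so each p-value measures only the spread between dates. The 2 libraries of a date correlated with a median of 0.9816 across genes, and libraries of different dates with a median of 0.9499, where genes are not independent replicates. Fold changes are differences of log2(FPKM + 1), given with their standard error, and group levels are means with the SD over dates.

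Expression followed the calendar in many genes, and genes without a call may do so too. In the simulated data 71% of seasonal genes with a 1.5-fold range were recovered. Seasonal genes split into a winter set and a summer set. Of the genes called seasonal, 2577 (29.3%) had their fitted peak in January, 2900 (32.9%) in July and 1944 (22.1%) in August, while April held 9 and October 18. The winter set included jpt2 (peak-to-trough range 3.26 on the log2 scale) and a cry1 copy, LOC101160902, a clock repressor gene, with a range of 5.41. The summer set included lhb, the beta subunit of luteinizing hormone, with a range of 4.30 and a July peak, and f13a1, the A chain of coagulation factor XIII, with a range of 6.08 and a June peak. The thyrotropin beta subunit gene tshb peaked at another time, in October, with a range of 2.25 (adjusted p = 0.00055). In all, 8808 of 16493 genes tested (53.4%) followed an annual curve by limma's F test. The median range among them was 0.57 on the log2 scale, and 1345 had a range of at least 1. Within the dates from July 2016 only, 7697 genes were called, of which 6910 were among the 8808. Within the dates to June 2016 only, 5295 were called, 4759 of them shared. Both date ranges, the step term and the July to September pairs were added after the data were seen.

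**Figure D1:**
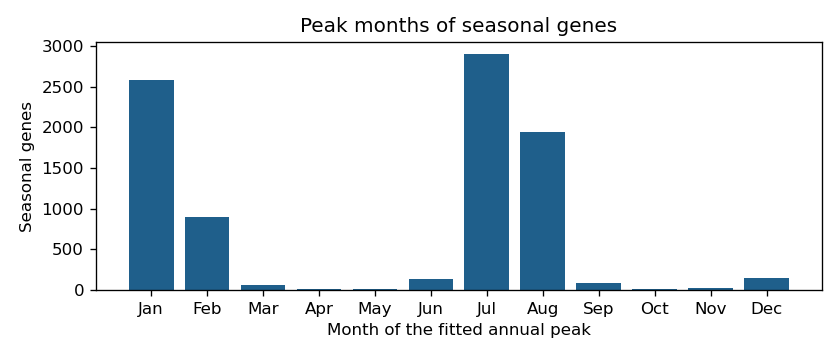
Number of seasonal genes (vertical axis) by the calendar month in which the fitted annual curve peaks (horizontal axis), over the 8808 genes called. January holds 2577 genes, July 2900 and August 1944, and April holds 9.

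The timing of these curves returned in the other year for most genes. Of 6888 genes called seasonal in the first year alone (October 2015 to September 2016, 12 dates), 5769 peaked within 45 days of the same calendar date in the second year, which is 83.8% (exact 95% interval 82.9 to 84.6). Of 6781 called in the second year alone, 5757 did so in the first, which is 84.9% (84 to 85.7). A uniformly random peak date would fall in that window in 25% of genes, but peaks crowd in winter and summer. Over all pairings of 1 gene's peak with any gene's peak in the other year, a comparison added after the result was seen, the share was 42.2% for the genes called in the first year and 45.4% for those called in the second. The intervals treat genes as independent, which they are not.

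Summer and winter brains differed in many genes, several pituitary hormone and clock genes among them. In June to August, lhb (100125483) stood at 188 ± 72.0 FPKM (SD, n = 6 dates) against 14.9 ± 10.3 in December to February, a rise of 3.68 ± 0.53 on the log2 scale (adjusted p = 5.57e-06). Prolactin, prl1, rose from 929 ± 201 to 3331 ± 1601 FPKM, by 1.73 ± 0.32. Somatolactin, smtl, rose by 1.66 ± 0.40 and tshb-like, annotated as a second thyrotropin beta subunit, by 1.63 ± 0.44. All 6 summer dates lay above every winter date for lhb and prl1, as did 5 for tshb-like and 4 for smtl. The winter mean of lhb includes February 2016 at 35.4 FPKM, where the other winter dates lay between 8.17 and 14.

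Of the 9 hormone genes tested, these 4 rose in summer and the other 5 did not pass (4 rose when adjusted over the list alone). By the annual curve 7 of the 9 were called seasonal, all but gh and pomc. Growth hormone, gh, stood at 1259 FPKM in summer and 1067 in winter. The shared alpha subunit cga stood at 785 and 616, pomc at 486 and 302, and fshb, the follicle-stimulating hormone beta subunit, at 192 and 120. The tshb gene stood at 0.492 and 0.723. With July to September against January to March pomc passed (0.86, adjusted p = 0.00585), and with libraries taken as separate samples pomc (0.0256) and fshb (0.0246) did. The genes gpha2 and prl were below the filter, with at most 0.41 and 1.04 FPKM in any library. Of 7 pituitary identity genes, 3 rose (six6 by 0.56, lhx3 by 0.57 and pou1f1 by 0.45) and gata2 fell by 0.55, and camera did not call the list. With quantile normalization 2 of the 7 rose.

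**Figure D2:**
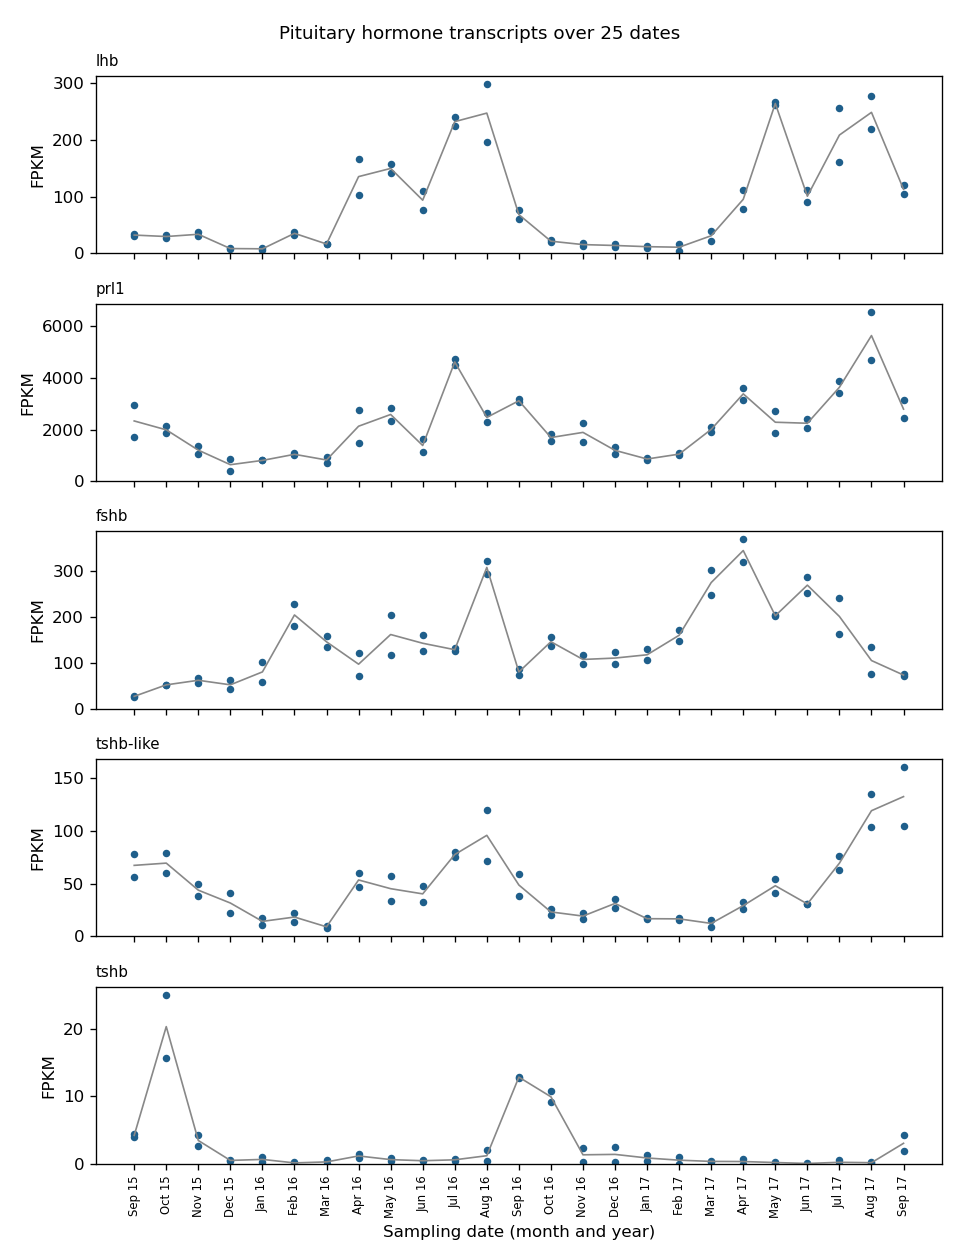
Deposited FPKM (vertical axes) of 5 pituitary hormone genes by sampling date (horizontal axis); points are single libraries and the line joins date means. Over dates, lhb runs from 8.17 FPKM in January 2016 to 264 in May 2017, and tshb reaches 20.3 in October 2015 and 12.8 in September 2016.

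The 10 named genes with the largest summer rise began with f13a1 (101168749), at 39.3 ± 17.8 FPKM against 0.516 ± 1.14 (4.81 ± 0.56). After lhb came fkbp1b (2.37), prmt2 (2.06) and gamt (2.06), an enzyme of creatine synthesis. The cry1 copy LOC101164536 rose by 2.02, neuropeptide B, npb, by 2.00, mllt11 by 2.00, the oxygen sensor egln3 by 2.00 and slc25a48 by 1.90. In each of these 10, all 6 summer dates lay above every winter date. Among genes higher in winter, cry1 LOC101160902 stood at 44.7 ± 10.8 FPKM against 0.839 ± 0.348 in summer (-4.62 ± 0.60). Next came jpt2 (-2.93), at 255 ± 48.5 against 32.3 ± 3.01 FPKM. Both the inositol-forming enzyme isyna1 (-2.83) and the inositol transporter slc5a3 (-2.29) were higher in winter. So were rybp (-2.78), matn3 (-2.69), the histone demethylase kdm7a (-2.49), dec1a (-2.37), mocs2 (-2.16) and the monocarboxylate transporter slc16a1 (-2.12). For slc16a1, 5 of 6 summer dates lay below every winter date, and for the other 9 all 6 did.

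Clock genes moved in both directions. Of 31 tested, 9 rose in summer, 15 fell and 7 did not pass (26 passed when adjusted over the list alone), and 25 followed an annual curve. The repressor cry2 (LOC101173389) fell by 1.26, bhlhe41 by 1.85, the kinase gene csnk1e by 0.91, and the per2 copy LOC101161338 from 51.4 ± 16.6 to 14.3 ± 2.77 FPKM (-1.73 ± 0.27). The other cry1 copies were LOC101167667 (-0.90) and LOC101174986 (-1.47), while arntl2 rose by 0.94. A second per2 gene stood at 6.65 FPKM in summer and 7.40 in winter and did not pass. Sampling at 1 clock hour means that the time since sunset differs between summer and winter dates, over a calculated range of 2.44 hours across the series.

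**Figure D3:**
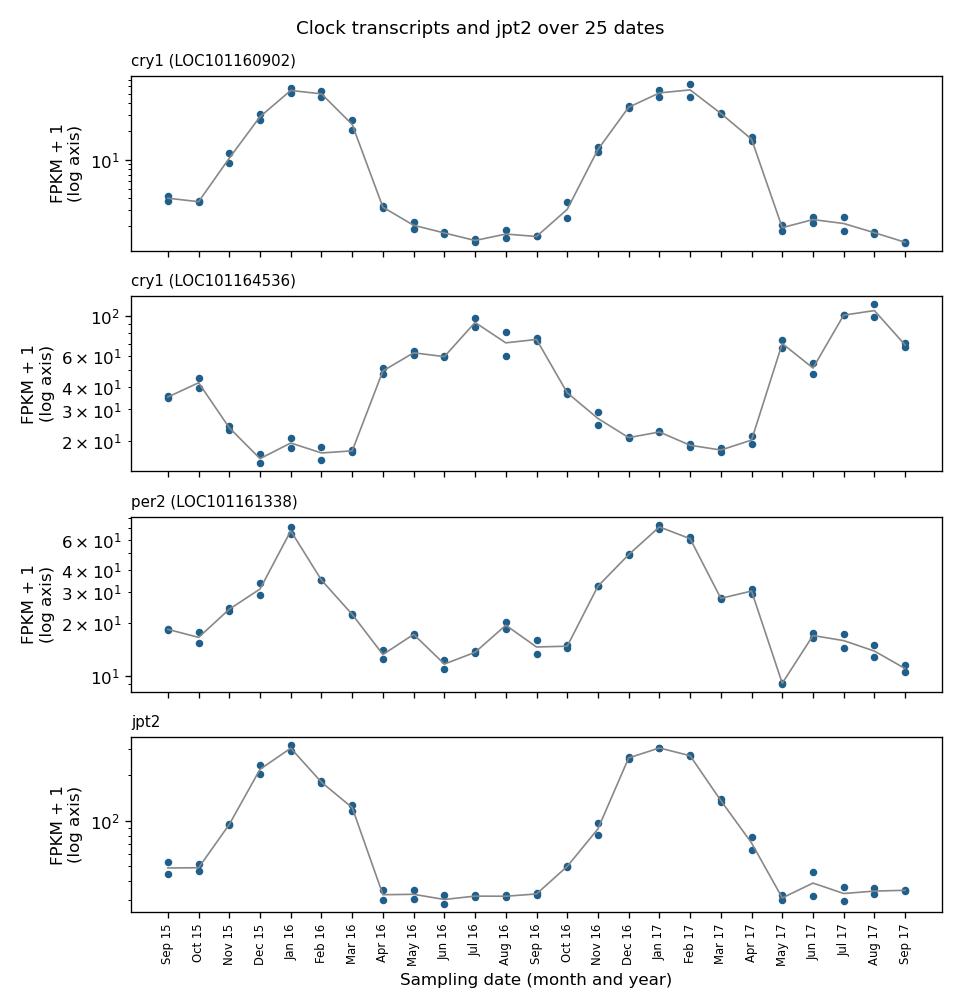
FPKM + 1 on log axes (vertical) of 2 cry1 copies, a per2 copy and jpt2 by sampling date (horizontal axis); points are single libraries and the line joins date means. The cry1 copy LOC101160902 has a mean of 44.7 FPKM over winter dates and 0.839 over summer dates, and the copy LOC101164536 has 18.1 and 79.1.

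Reproductive and photoperiod genes changed in part. Of 13 sex steroid genes, 8 rose in summer and 2 fell (11 passed when adjusted over the list alone). Brain aromatase, cyp19b, which makes estrogen, rose from 122 ± 41.0 to 251 ± 53.2 FPKM (1.07 ± 0.21), hsd17b3 by 1.09, hsd17b4 by 0.71 and cyp17a2 by 0.75. The estrogen receptor esr1 stood at 3.67 and 3.47 FPKM. With July to September against January to March, cyp19b no longer passed (0.36, adjusted p = 0.248), nor did tshr (0.26, adjusted p = 0.144). Of 19 photoperiod and thyroid hormone genes, 6 rose, 1 fell and 12 did not pass (6 passed when adjusted over the list alone). With quantile normalization 4 rose and 1 fell, and under median ratio scaling 5 and 2. The receptor gene thrb and the transporter gene slco1c1 (LOC101173674) each rose by 0.51. The receptor gene tshr passed narrowly (0.36, adjusted p = 0.038). It lost its call under several settings, among them quantile normalization (adjusted p = 0.175), and without December 2016 replicate 2 (0.0601), February 2017 replicate 2 (0.0589) or August 2017 replicate 1 (0.0797). The deiodinase genes dio2 and dio3 did not pass, at 6.27 and 2.75 FPKM in summer against 4.09 and 3.52 in winter. On the dates from July 2016 only dio2 did pass (0.72 against 0.47 over all dates, adjusted p = 0.00839), as it did with a step term (0.53, adjusted p = 0.043), without June 2016 replicate 2 (0.50, adjusted p = 0.0452) or July 2016 replicate 1 (0.53, adjusted p = 0.0491), and with libraries as separate samples (adjusted p = 0.015).

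Of 38 hypothalamic neuropeptide genes, 12 fell in summer, 5 rose and 21 did not pass (14 passed when adjusted over the list alone). June 2016 is the only summer date before July 2016, while the winter dates from December 2015 to February 2016 all precede it. Some members, such as gnrh2, fell in a step at July 2016, which can add to the falls in summer. The list was not recounted with a term for that step. Tachykinins fell, tac1 by 1.08 and tac3 by 1.24, as did cart-ch3 by 0.69, while vip rose by 1.24. The reproductive peptides gnrh1 (3.67 and 4.39 FPKM), gnrh3 (7.01 and 9.96) and kiss2 (7.75 and 6.68) did not pass. Of 10 non-visual opsins, opn3 rose by 0.56 and opn4a fell by 0.60, and valop (1.85 and 2.05 FPKM) was among the 8 that did not pass. The cold-inducible gene cirbp stood at 1176 and 993 FPKM and did not pass, but it did with July to September against January to March (0.41, adjusted p = 0.0379).

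Proliferation, interferon and immediate early genes were called mostly in 1 direction, higher in summer. Of 13 proliferation genes, 9 rose and 1 fell (10 passed when adjusted over the list alone), with pcna from 10.4 ± 0.712 to 19.9 ± 3.05 FPKM (0.88), mcm7 up by 0.81, cdk1 by 1.28 and top2a by 1.00. Of 13 interferon and antigen presentation genes, 9 rose (10 over the list alone), with tap1 up by 0.83 and irf9 by 0.79. Of 17 immediate early genes, 10 rose (10 over the list alone), with klf2 up by 1.15, dusp1 by 1.02, jund by 0.74 and jun by 0.74. Of 38 chaperone genes, 12 rose and 3 fell (12 over the list alone), with chordc1 up by 1.23, and hspa13 down by 0.92 and cct2 by 0.62. The chaperone split was 12 and 6 with quantile normalization and 11 and 7 under median ratio scaling.

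Single markers of cell types moved as well, with no list called by camera. Of 17 oligodendrocyte markers, 9 rose and 1 fell (10 over the list alone), with olig1 from 0.613 to 4.71 FPKM (1.81), cd59 up by 1.34 and cnp by 0.50. Of 16 neuron markers, 8 rose and 1 fell (9 over the list alone), with gap43 up by 0.94, syt1 by 0.38 and elavl4 by 0.42. Of 11 microglia markers, 3 rose and 4 fell (7 over the list alone), among them apoeb, down from 619 ± 115 to 192 ± 33.6 FPKM (-1.68), p2ry12 (-0.91) and aif1 (0.93). Radial glia markers gave 2 higher and 3 lower of 13 (5 over the list alone), with glul-like (LOC101163918) up by 1.61 and aqp1 by 1.16. Endothelium gave 3 higher and 2 lower of 13 (5 over the list alone), erythrocytes 4 and 3 of 11 (7), and cilia 4 and 3 of 10 (7). With quantile normalization cilia gave 2 and 3.

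By limma, 8990 genes (54.5% of those tested) differed between summer and winter, 5107 higher and 3883 lower in summer, of which 952 differed at least 2-fold. The excess of higher genes depends on the scaling: the split was 4441 and 4530 with quantile normalization and 4565 and 4528 under median ratio scaling. None of the 24 lists of at least 5 genes was called by camera, a limma test of a list against all other genes. At an unadjusted p below 0.05 it gave 6 lists, and 0 with an estimated correlation. Within the dates from July 2016 only, 8036 genes were called, of which 7279 were among the 8990.

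Days of like length in spring and autumn did not carry like expression. The comparison sets months of shortening days against months of lengthening days at a matched day length. The fish lived at natural temperature, which was not analysed here. An effect of the direction of day length cannot be told apart from temperature or other differences between these months. August to October had a mean day of 11.86 hours and February to April one of 11.97 hours. Thyrotropin genes were higher as days shortened in the months chosen. The tshb gene stood at 7.40 ± 7.31 FPKM (SD, n = 7 dates) against 0.512 ± 0.363 (n = 6 dates), a rise of 1.93 ± 0.44 (adjusted p = 0.00637), and tshb-like at 79.2 ± 38.6 against 23.1 ± 16.3 (1.78 ± 0.37). Of the 7 falling dates, 5 lay above every rising date for each gene. In the other direction fshb stood at 113 ± 93.5 FPKM in falling and 204 ± 90.8 in rising days (-1.09 ± 0.38, adjusted p = 0.0403).

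Clock genes again carried some of the largest differences. This contrast shares its August dates with summer and its February dates with winter. A gene named in both contrasts is therefore not found in separate data. The cry1 copy LOC101160902 was lower in falling days, at 1.42 ± 1.09 against 28.9 ± 19.7 FPKM (-3.29 ± 0.49), and LOC101164536 was higher (1.42 ± 0.25). The copies LOC101167667 (-0.56), LOC101174986 (-1.10) and the per2 copy LOC101161338 (-0.90) were lower too. Other named genes higher in falling days were cnot6l (23.3 against 7.17 FPKM), the myoglobin gene mb (1.37), the Wnt inhibitor sfrp5 (1.26), prmt2 (1.21), the globin hba1 (1.18), ten1 (1.14) and the Notch target hes1 (1.13). For cnot6l, sfrp5 and hes1 all 7 falling dates lay above every rising date. Lower in falling days were the globin hbae (LOC101155030, -1.91), matn3 (-1.65), rybp (-1.60), mocs2 (-1.54), kdm7a (-1.52), jpt2 (-1.49), slain1 (-1.47), gb (-1.43) and gatm (-1.37), the first enzyme of creatine synthesis. The rising mean of hbae includes April 2017 at 85.1 FPKM, where the other rising dates lay between 6.31 and 17.4.

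Of 31 clock genes, 9 were higher in falling days and 12 lower (23 passed when adjusted over the list alone), with bhlhe41 at -1.35 and arntl2 at 0.71. Of 9 hormone genes 2 were higher, 1 was lower and 6 did not pass (3 over the list alone). Prolactin (0.80, adjusted p = 0.0804), smtl (0.78) and lhb (0.97) were among those 6, as were gh (718 and 975 FPKM in falling and rising days), cga (614 and 866) and pomc (387 and 274). Of 38 neuropeptide genes, 3 were higher and 7 lower (12 over the list alone), with tac1 at -0.72, cart-ch3 at -0.54, nmb at -0.45 and sst2-like at 0.46. Before July 2016 lie only September and October 2015 of the falling dates, and February to April 2016 of the rising ones. The step at July 2016 can therefore add to this count, which was not repeated with a step term. Of 13 proliferation genes 5 were higher (5 over the list alone), with pcna at 0.64 and cdca8 at 0.61. Of 17 oligodendrocyte markers 4 were higher (4 over the list alone), with olig1 at 1.21 and gpr17 at 0.80, and 13 did not pass. The always-named genes cirbp, cyp19b, dio2, dio3, tshr, gnrh1, gnrh3, kiss2, esr1, per2, opn4a and valop did not pass. Some genes that did not pass did so under other settings. For esr1 this held in 7 of the 50 fits with 1 library left out (adjusted p = 0.0404 to 0.0499) and with the date as a random effect (0.0426), where cyp19b (0.0328) and prl1 (0.0389) passed too. With September to November against March to May cyp19b was lower (-1.26, adjusted p = 0.00744). On the dates from July 2016 only opn4a was lower (-0.63, adjusted p = 0.0182), also with a step term (-0.40, adjusted p = 0.0345), and on the dates to June 2016 only gh was (-2.83, adjusted p = 0.0453). Libraries as separate samples gave calls for gh, cga, prl1, cyp19b, per2, esr1 and opn4a. The replicate block gave them for prl1, lhb, cyp19b, esr1 and opn4a. It too was fitted on single libraries and ignores the shared date, so it is no separate check.

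By limma, 3626 genes (22% of those tested) differed, 2131 higher and 1495 lower in falling days. The split was 1817 and 1912 under median ratio scaling and 1869 and 1933 under quantile normalization. None of the 24 lists was called by camera (4 at an unadjusted p below 0.05, and 0 with an estimated correlation). Within the dates from July 2016 only, 3878 genes were called, 2786 of them shared, and within the dates to June 2016 only, 1. The count depends on the months chosen: September to November against March to May, where mean day length was no longer matched (11.02 and 13.04 hours), gave 6 genes, 1 of them shared, in which tshb kept its call (2.17, adjusted p = 0.00744), tshb-like lost it (0.81, adjusted p = 0.998) and rybp, mocs2 and kdm7a changed sign. The tshb call was lost on the dates from July 2016 only (1.61, adjusted p = 0.0555), where tshb-like kept its own (1.89, adjusted p = 0.0137), and both were lost on the dates to June 2016 only (2.80 and 1.66, adjusted p = 0.792 each). The hba1 call was lost on the dates from July 2016 only as well (0.69, adjusted p = 0.311). The fshb call was lost with quantile normalization (adjusted p = 0.0543), with no filter (0.0575), with September to November against March to May (0.366), on the dates from July 2016 only (0.064) or to June 2016 only (0.424), and without April 2016 replicate 1 (0.0604) or August 2017 replicate 2 (0.0549).

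Between the years several genes fell in a step at July 2016, which 9 of the 12 month pairs straddle. The peptide gene gnrh2 (100049219) lay between 13.7 and 29.4 FPKM in all 20 libraries to June 2016 and between 0 and 0.82 in the 30 libraries from July 2016. The relaxin family gene rln3a went from 4.01 to 33.6 FPKM before that date to 0 to 1.06 after it, and cart-ch4 from 8.04 to 30.7 to 0 to 0.44. Between years (October to September, month by month) cart-ch11 fell from 32.9 ± 21.7 to 1.53 ± 1.64 FPKM (SD, n = 12 dates), and pth2 from 2.36 ± 1.12 to 0.407 ± 0.187. With a term for dates from July 2016 in the annual curve, 4795 genes were called for that term, 1225 higher and 3570 lower. The term compares the dates before and from July 2016 only. No other date or gradual drift was compared with it, and the split was not repeated under other scalings.

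Markers of brain regions also differed between the dates before and from July 2016. Of 17 midbrain and hindbrain markers other than gnrh2 and rln3a, 11 were lower from July 2016, with a median of -0.49 on the log2 scale. Of 16 telencephalon markers 9 were higher and 4 lower, with a median of 0.24. Both lists were written after the fall of gnrh2 was seen. Between years, zic1 fell from 38.9 to 29.1 FPKM (-0.40), dlx5 rose from 18.6 to 25.8 (0.48) and dlx2 from 9.78 to 12.6 (0.34).

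**Figure D4:**
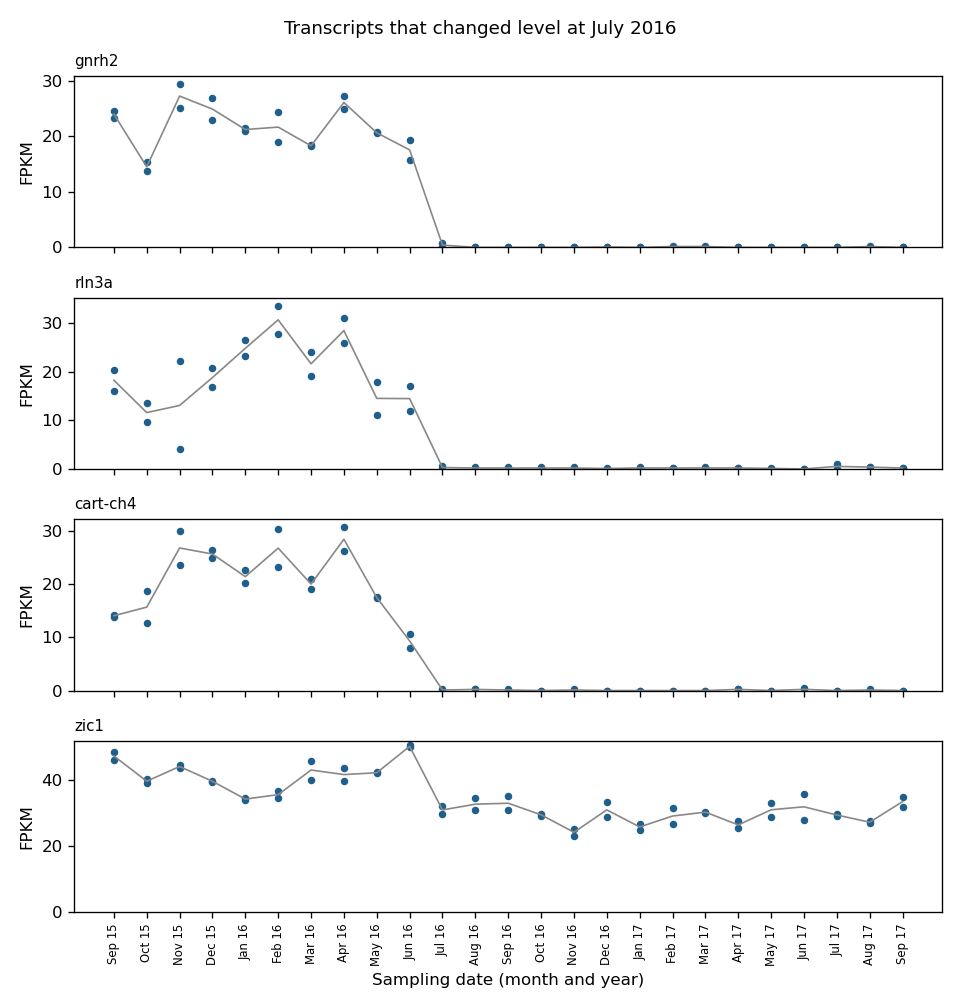
Deposited FPKM (vertical axes) of gnrh2, rln3a, cart-ch4 and zic1 by sampling date (horizontal axis); points are single libraries and the line joins date means. From July 2016 on gnrh2 stays at or below 0.82 FPKM, rln3a at or below 1.06 and cart-ch4 at or below 0.44, while zic1 stays between 23.1 and 35.8.

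Other groups shifted between the years too, as did the genes as a whole, with 1479 lower and 496 higher. Some lists without a camera call also had more genes lower than higher. Others did not, such as pituitary hormones with 0 lower and 1 higher of 9, and sex steroid genes with 1 and 1 of 13. Neuropeptides gave 11 lower and 4 higher of 38, radial glia 4 and 0 of 13, cilia 3 and 0 of 10, and endothelium 3 and 1 of 13. With quantile normalization these were 9 and 5, 4 and 1, 1 and 0, and 2 and 1. Of 17 oligodendrocyte markers 9 fell (12 over the list alone), with mpz from 87.2 to 58.7 FPKM (-0.59) and mag from 58.1 to 41.6 (-0.49). Camera called this list lower (adjusted p = 0.000115; adjusted p = 0.657 with an estimated correlation). Of 55 oxidative phosphorylation genes 18 fell (39 over the list alone), with ndufa5 at -0.34 and atp5pf at -0.39, and camera called it lower (adjusted p = 3.08e-08; adjusted p = 0.657 with an estimated correlation). Of 65 ribosomal protein genes 16 fell (35 over the list alone), with rps9 at -0.30 and rps28 at -0.33 (adjusted p = 2.54e-07; adjusted p = 0.657 with an estimated correlation). With quantile normalization 8 ribosomal genes were lower and 2 higher, and camera did not call the list (adjusted p = 0.185).

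Of 7 pituitary identity genes 3 rose (5 over the list alone), six6 by 0.27, lhx3 by 0.26 and nr5a1 by 0.41 (adjusted p = 0.00031; adjusted p = 0.275 with an estimated correlation). Of 13 interferon genes 2 fell (2 over the list alone), tapbp by 0.40 and mx (LOC101163162) by 0.48 (adjusted p = 0.0495; adjusted p = 0.657 with an estimated correlation). The chaperone list was called higher by camera (adjusted p = 0.0495, and 0.762 with an estimated correlation), though none of its 38 genes was called alone by limma. Both quantile normalization (adjusted p = 0.0988) and a pseudocount of 0.1 (adjusted p = 0.0581) ended the camera call.

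Single genes with the smallest adjusted p were higher in the second year for smad2 (0.35), vip (0.55), tcf12 (0.34), cers6 (0.34) and slc7a5 (0.43). They were lower for draxin (-0.97, from 11.0 to 4.80 FPKM), syk (-0.51), pla1a (-0.66), ppara (-0.52) and rab21 (-0.34). All 12 months showed the direction for each of these except slc7a5 and syk, with 11. Among the always-named genes, gnrh1 fell from 5.69 to 3.30 FPKM (-0.68), valop from 2.81 to 1.22 (-0.76) and cirbp from 1066 to 872 (-0.31). In the same set pomc rose from 284 to 396 FPKM (0.51), opn4a by 0.33 and cry1 LOC101174986 by 0.51.

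By limma, 1975 genes (12% of those tested) differed between the years, 496 higher and 1479 lower. The split was 850 and 964 under quantile normalization and 816 and 999 under median ratio scaling. In the July to September pairs, which all fall after the step, 11 genes were called, all higher in the second year, and none of the 10 named genes passed (adjusted p = 0.109 to 0.411). All 10 kept their direction. The change was larger than over all pairs for smad2 (0.41) and tcf12 (0.42) and smaller for the other 8, among them draxin (-0.29), ppara (-0.37) and rab21 (-0.25). With 3 pairs, lost calls do not tie the difference between years to the step.

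Some genes rose and fell more than once a year. The zinc finger gene trafd1 was high in spring and autumn of the first year, at 57.5 FPKM in October 2015, 25.7 in January 2016, 51.7 in April 2016 and 26.3 in July 2016. It showed no call for the annual curve (adjusted p = 0.912). By limma's F test, a 6-month wave improved on the annual curve in 1383 genes, and the smallest adjusted p (0.000544) went to jpt2, usp19, pnrc2, trafd1 and ccdc106. For jpt2 the 6-month wave went with a narrow winter peak, with 302 FPKM in January 2016 and 31.5 by April 2016.

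A change in the shape of the annual curve between the years was called in 5 genes, with 2953 at an unadjusted p below 0.05. They were hspb11, ube2l3, and outside the naming rule, chosen after their values were seen, LOC101172909, LOC101164657 and BGI_novel_G001489. The range of hspb11 went from 0.11 on the log2 scale in the first year to 1.61 in the second (adjusted p = 0.0434), and the fitted peak of ube2l3 moved from July to December. Of the 50 omissions of 1 library, 22 ended the call of hspb11 and 25 that of ube2l3, and with no filter both calls ended (adjusted p = 0.0892 each), as did that of hspb11 with the date as a random effect (0.0632). Without March 2016 replicate 2 or November 2016 replicate 2 the count was 0, and without January 2016 replicate 2 it was 27.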

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

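The tests of the July 2016 fall and of the hormone ratios were chosen only after the result was seen, while the sunset test and the splits of the dates were set before.

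The transcripts gnrh2, rln3a and cart-ch4 fell from July 2016 to near 0 and stayed there, in all 30 later libraries. The bound set for lower depth as a cause was a fall of depth more than 10-fold. FPKM is already scaled by library size, so even such a fall need not lower it. The median relative depth from July 2016 was 0.971 of the earlier one. That depth hardly differed argues against lower depth as the cause. A candidate explanation is that the dissected block held less midbrain and hindbrain tissue: 17 other markers of these regions had a median step of -0.49, below the 2.5th percentile of random lists matched on level (-0.167), 13 of them below 0. Telencephalon markers had a median of 0.24. Both medians compare the dates before and from July 2016, with no other date or gradual drift tried, and are far smaller than the fall of gnrh2. A different stock, cohort or age of fish from that date stays open and was not tested, and the year comparison cannot be separated from this step in 9 of its 12 month pairs.

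The rise of pituitary hormone transcripts in summer may reflect a larger share of pituitary in the block, which would raise all its hormones alike. For lhb this is argued against as the whole cause. Its ratio to the other measured hormones, tshb near the floor among them, was 2.85 higher in summer on the log2 scale (exact two-sided permutation p = 0.00216, the smallest possible for 6 against 6 dates). The ratios of prl1, smtl and tshb-like to lhb were lower in summer (-1.95, -2.02 and -2.04, adjusted exact p = 0.00758 to 0.0152). But lhb was taken for its rise, the largest among these hormones on the same dates, and the permutations did not repeat that choice. A larger share as part of the lhb rise stays open. The ratio to the mean of the others was 0.65 higher for prl1 (exact p = 0.0195), and did not pass for smtl (0.57, exact p = 0.149) or tshb-like (0.55, exact p = 0.0996), but that mean includes the other risen hormones. Taken against each of 7 hormones measured in both seasons, prl1, smtl and tshb-like were each higher relative to 3, namely gh (by 1.48, 1.41 and 1.39), cga (1.42, 1.35 and 1.33) and pomc (1.17, 1.1 and 1.08), with adjusted exact p of 0.00758 to 0.0455. Of 924 regroupings of the 12 dates, 1, 6 and 4 gave as many. These ratios cannot decide whether a larger share is the whole cause. The 3 hormones were taken because they had risen, while gh, cga and pomc had not passed, on the same dates. The regroupings did not repeat that choice. Of 7 pituitary identity genes, 3 rose in summer and 1 fell. A larger share, as all or part of the cause of these 3 rises, stays open. A first bound, at least 4 of the 7 hormones, was missed. It was replaced by the count of regroupings after that was seen, since it could be met only if each hormone that had not risen passed, and fshb did not (adjusted exact p = 0.109 to 0.206). A changed mix of cell types within the pituitary, or a dissection that took more of 1 part of it, was not tested. Seasonal change within the pituitary remains a hypothesis, since it was found and tested on the same data.

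Clock genes differ between seasons at a single sampling hour, so the time since sunset is a possible explanation. With hours since sunset in the model, 20 of the 21 clock genes called between falling and rising days stayed called. The term could take away little there, since the months were chosen for like day length. Mean hours since sunset were 2.21 in falling and 1.9 in rising days, up to a constant set by the longitude. The kept calls are therefore no separate evidence. That these genes differed at close times since sunset argues against that time as the whole cause there. Between summer and winter the time since sunset moves with day length and was not separated. Water temperature was not analysed here and stays open.

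In 12 of 170 groups of dates 1 date lay far from the others; chance gives about 1 in 20. In February 2016, lhb stood at 35.4 FPKM and f13a1 at 2.84, where the other winter dates lay at 8.17 to 14 and 0.015 to 0.125. In April 2016 the rising-day values were 48.3 for cry1 LOC101164536 (others 16.2 to 19.2), 9.82 for dio2 (2.78 to 4.49), 8.74 for prmt2 (0.59 to 2.15) and 4.08 for rybp (23.7 to 42.4). In June 2016 per2 stood at 5.24 (6.54 to 7.42) and esr1 at 1.89 (3.72 to 4.52) among summer dates. The remaining ones were gnrh3 at 2.65 in March 2017 (6.64 to 13.1), cry1 LOC101174986 at 2.70 in August 2017 (0.51 to 1.14), matn3 at 1.47 in June 2017 (0.46 to 0.77) and hbae LOC101155030 at 85.1 in April 2017 (6.31 to 17.4).

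The annual curve differed between the years by limma's test in hspb11, ube2l3 and BGI_novel_G001489 (adjusted p = 0.0434 each) and in LOC101172909 and LOC101164657 (adjusted p = 0.0328 each). Chance cannot be excluded for this count: 11 of 100 splits of the dates, the real one included, gave at least 5 genes. The highest of the others gave 2649, and why was not tested. In an earlier draw the highest was far lower, so this figure depends on the splits drawn.

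The other counts met the bound set beforehand on the share of regroupings that reach the real count. This does not exclude chance, since regrouping treats the dates as exchangeable. Libraries of neighbouring dates were more alike, with a median correlation of 0.9711 against 0.9499 for all different dates. Of 100 regroupings of the dates, 1 (the real one) reached the 8808 seasonal genes, and the highest of the others gave 1. For summer against winter 1 did (8969 genes in a fit of the 12 dates, highest other 4007), for falling against rising days 1 (2538 in a fit of the 13 dates, highest other 2), and for the 6-month wave 1 (1383, highest other 824). Between years 2 of 100 reached 1975, and the other gave 3315. That split exchanged August and September between the years. Its 9 other pairs that straddle July 2016 carry the step as the real grouping does, while the 4 exchanged dates all lie after it, so its excess over the real count was not explained. The year splits were drawn a second time, from another seed and after the first draw had been seen, so that the exchanged months could be recorded. The counts here are from the second draw. In both draws the year comparison met the bound and the annual curves between years did not. Within the July to September pairs 11 genes were called.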

How the results depend on the processing

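The step term, the dates to or from July 2016 and the July to September pairs were chosen only after the data were seen. Counts stayed within 1.5 times the reported one, except as follows, and where no construction is named the cause was not tested. Libraries as separate samples ignore the shared date and add degrees of freedom. They gave 6951 (falling against rising days), 5984 (years), 4565 (6-month wave) and 3248 (annual curves between years). The replicate block, also fitted on single libraries without the date, gave 6940, 5952, 4524 and 3210. The replicate numbers carried no shared signal across dates (median correlation 0.01 over 276 date pairs). For annual curves between years, the date as a random effect gave 453, no filter 0 (limma) and a filter at 5 FPKM 3; 25 of 50 single omissions moved it, from 0 to 27. A 2-fold threshold gave 952 (summer against winter) and 121 (falling against rising), a stricter rule. September to November against March to May, at unmatched day lengths, gave 6, with rybp at 0.231, mocs2 at 0.001 and kdm7a at 0.297, against their reported direction. Fewer dates to June 2016 gave 5295 seasonal genes and 1 gene for falling against rising, where kdm7a stood at 0.001. July to September pairs gave 11 for the years. The repeat of the peak date was 82.4% with no filter, and 82.7 to 85.3% and 83.7 to 86% with single libraries left out. With an estimated correlation camera called 0 lists between years (1 at an unadjusted p below 0.05). Single omissions left 8634 to 8874 seasonal genes, 8846 to 9039 for summer against winter, 3436 to 3712 for falling against rising, 1784 to 2111 between years and 1241 to 1458 for the 6-month wave. With the step term the counts were 9642 (seasonal), 9502 (summer against winter), 4352 (falling against rising) and 1991 (6-month wave). Of the named genes' values and the camera results of the lists, over all settings, 7898 kept their side of the threshold, 140 lost a call, 50 gained one and 4 changed sign. Depth per library is known only relatively, so limits on low genes were not set.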

Other observations

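No test in this part was chosen only after its result was seen.

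Lipid and metabolic genes changed in both directions between summer and winter. Of 19 fatty acid synthesis genes 4 were higher in summer and 3 lower (7 when adjusted over the list alone), with acsl3 up by 1.02, and the desaturase scd (LOC105353580) down from 57.0 to 20.5 FPKM (-1.43) and fasn by 1.34. Of 20 cholesterol synthesis genes 4 were higher and 5 lower (9 over the list alone), with nsdhl up by 0.72, ebp by 0.89 and fdft1 down by 0.90. Of 17 NRF2 genes 6 were higher and 5 lower (11 over the list alone), with catalase, cat, up by 0.85, and sqstm1 down by 1.16 and hmox1 (LOC101174976) by 1.34. Of 15 insulin and growth genes 6 were higher and 2 lower (8 over the list alone), with foxo3 up by 0.96 and sesn1 down by 0.61.

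Of 55 oxidative phosphorylation genes 14 were higher in summer and 8 lower (20 over the list alone), with ndufa2 up by 1.06; the split was 13 and 15 under median ratio scaling. Of 65 ribosomal protein genes 4 were higher and 14 lower (12 over the list alone), with rplp0 down by 0.66, and with quantile normalization 19 were higher and 9 lower, so the list has no stable direction. The muscle gene actn3, the only muscle marker tested, rose from 0.249 to 2.31 FPKM (1.25). Both retina and pineal markers tested, aanat1b and rpe65, did not pass between summer and winter, at 0.13 and 0.10 on the log2 scale.

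Median and mean log2 change between summer and winter differed in sign for NRF2 genes (0.09 and -0.05), microglia markers (0.03 and -0.10), radial glia markers (-0.03 and 0.12), endothelium (-0.01 and 0.05) and non-visual opsins (-0.01 and 0.01). For erythrocyte markers the median was 0.18 and the mean 0.09, while camera, which compares a list with all other genes, gave the direction down without a call.

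Leaving out 1 library moved the count of 5 genes with a different annual curve as follows. It was 9 without November 2015 replicate 1, 8 without March 2016 replicate 1 and 27 without January 2016 replicate 2. It was 0 without March 2016 replicate 2 or November 2016 replicate 2, and 1 without February 2016 replicate 2 or December 2016 replicate 1. It was 3 without replicate 1 of January, February or April 2016 and without replicate 2 of May or June 2017. It was 2 without replicate 1 of October 2015, May, June or July 2016, or February, May or August 2017, and without replicate 2 of November 2015, October 2016, or January, March, July or September 2017.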
